A study of Mus musculus with 60 samples.

How the data were processed

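Cecal contents of 60 ICR mice, an outbred laboratory stock, were frozen, total DNA was extracted and 16S rDNA libraries were sequenced on an Illumina HiSeq, per the labels' protocols. The 16S rDNA gene is carried by all bacteria, and its sequence differs between them, so that reads can be grouped into operational taxonomic units (OTUs). The authors deposited a table of counts, with 1 row for each of 1544 OTUs and 1 column for each library; its values are whole numbers with a different total in each mouse, and were taken as raw counts. The clustering tool, the identity threshold, the amplified region and any removal of chimeras or rare OTUs are not given in the sources used here. These steps set how many OTUs a mouse can show, so numbers of OTUs hold for this table and not for the gut as such. The table pairs no OTU with a taxonomic name. Comparisons planned for genera were therefore made on OTUs, as the design foresaw for a table without taxonomy, and the planned taxon lists and phylum shares were not run. OTU numbers are printed as identifiers: each comparison contributes at most 2 that rose and 2 that fell, beside 3 of the most abundant OTUs of the table. The values of such an OTU in further comparisons were added after they were seen.

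Mice were assigned to 6 groups of 10 from the treatment label of each sample. The titles give each mouse a number within its group, and columns of the table were matched to titles by name. A further 79 columns belong to other samples and were not used. Of the OTUs, 1378 had at least 1 count in the 60 mice. Total counts per mouse lay between 34794 and 53189 (median 48245.5), with 2856921 counts in all. A count of 0 allows a share of up to 0.00862% in the shallowest mouse and 0.00564% in the deepest, from a floor of 3 counts. Reads of PCR products without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. No pair of mice had identical counts. The lowest Bray-Curtis distance between any 2 mice was 0.255, against at most 0.0463 between 2 random redraws of the counts of 1 mouse. This shows that no library was a resampling of another, but cannot tell 2 libraries of 1 mouse from those of 2 mice, and each sample was taken as 1 mouse.

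Differences per OTU were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM factors, robust fitting and the full count totals as library sizes. OTUs entered a comparison with a count in at least 5 of its mice and at least 20 counts in all. Each comparison was fitted on its 2 groups, and an OTU was called at a Benjamini-Hochberg adjusted p under 0.05 over the OTUs tested. A difference of differences over the control, AOS, model and AOS-treated model mice set the AOS contrast with the model against that without it. Among called OTUs with a mean share of at least 0.1% in either group, those with the largest fitted rise and fall were named, by a rule set in advance. The 6 comparisons, the distance to control, the counts of OTUs that moved back, the difference of differences, their tests and most alternatives were chosen before the data were examined. The overlap of OTU lists, the shares of OTU sets, the distances within groups and the values without a leading OTU or mouse were added after the results were seen. Distances within groups are given as values only: permutation tests of them were run and are not reported, since the mice of a group share these distances and are not independent in them. The fold of an OTU with no count in a group is given as a lower bound against 3 counts over that group. With 1 to 3 counts in a group, the fold is the ratio of pooled shares with its 95% counting interval (exact binomial). Fitted log2 fold changes of such OTUs depend on a prior count and are not printed.

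The natural-log Shannon index, inverse Simpson index, number of observed OTUs and Chao1 estimate were computed per mouse from counts as deposited. Group means were compared with 2-sided permutation tests of 100000 resamples (scipy 1.17.1), adjusted by Benjamini-Hochberg over the 6 comparisons. Communities were compared by PERMANOVA on Bray-Curtis distances of OTU shares with vegan 2.7.1, adjusted in the same way, beside a permutation test of the spread of mice around their group centroid. Closeness to the control mice was each mouse's mean Bray-Curtis distance to the 10 control mice.

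The edgeR procedure was tested on data simulated from each comparison's mean shares over both groups and its fitted spreads, with a part of the OTUs changed, in 5 simulations each. For the model against control mice, over 678.6 OTUs tested on average, it called 57.6% of OTUs changed by a log2 fold of 4, 93.2% at 6 and 8.2% at 2, and 7.06% of calls were false. For AOS against control mice these shares were 76.6%, 97.0% and 15.1%, with 8.65% false, over 726.8 OTUs. For the recipients of the 2 donor kinds they were 91.1%, 98.3% and 33.3%, with 5.79% false, over 458.2 OTUs. For AOS-treated model mice, AOS-donor recipients and control-donor recipients against model mice, 68.5%, 76.4% and 66.7% were called at a log2 fold of 4, over 541.2, 549.2 and 538.4 OTUs. Smaller changes are thus mostly missed.

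Alternatives covered other scaling factors (TMMwsp, total counts), DESeq2 1.42.0 with poscounts size factors, limma 3.58.1 on centred log-ratio values with a pseudocount of 0.5 counts, other filters, rarefied counts, all groups in 1 fit, the mouse number as a block and each mouse left out in turn. Other distances (Aitchison, Jaccard on presence) and other diversity indices were run as well. Other splits of the mice, 100 per comparison, gave the number of calls that regrouping yields.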

Results

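The data describe the bacterial community of the cecum, the pouch at the start of the large intestine, in 60 ICR mice aged 10 weeks. The 6 groups of 10 mice were a control group, a group given AOS at 10 mg/kg, a group on a high fat diet with STZ, and 3 further groups with that diet and STZ. STZ (streptozotocin) is a toxin of insulin-producing cells that is widely used with high fat diet to make a diabetes model, and mice with both are called model mice here. Of the 3 further groups, the first received AOS at 10 mg/kg, the second a fecal microbiota transplant (FMT) named for AOS at 10 mg/kg, and the third a transplant named for control. They are called AOS-treated model mice, AOS-donor recipients and control-donor recipients. The labels do not spell out AOS, nor say which animals were donors or when transplants were given. The study's title names a rescue, by the AOS transplant, from effects of the diet and STZ on the cecum, and the comparisons follow from that. Total counts per mouse ran from 34794 to 52956 in control, 37776 to 49115 in AOS, 41609 to 52269 in model, 46085 to 49387 in AOS-treated model mice, 47044 to 53189 in AOS-donor recipients and 47931 to 52693 in control-donor recipients. The title numbers were taken to mark separate mice, which the labels do not state, and p-values measure the spread between these samples.

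OTU1 had the highest mean share in 4 of the 6 groups, and OTU2 in the recipients of either transplant. OTU1 held 10.9% ± 18.9 of counts in control mice (SD, n = 10, as for all shares below), 10.7% ± 9.55 in AOS mice and 23.7% ± 13.2 in model mice. It held 14.4% ± 6.93, 12.9% ± 8.06 and 17% ± 12.5 in AOS-treated model mice, AOS-donor recipients and control-donor recipients, and passed the edgeR test in none of the 6 comparisons. OTU2 held 0.736% ± 1.24 in control, 0.884% ± 0.831 in AOS and 0.643% ± 1.56 in model mice. Its share was 12.2% ± 9.04, 18.8% ± 5.59 and 19.3% ± 10.2 in the 3 treated model groups, each above the untreated model mice (edgeR quasi-likelihood test, adjusted p = 0.0125, 0.00272 and 0.00318; log2 fold change 4.09, 4.56 and 5.11). In these groups 8, 10 and 9 of 10 mice lay above the mean of untreated model mice. OTU3 had no count in any control mouse and 7 counts over 2 of 10 AOS mice. In model mice it was found in 9 of 10 at 1.75% ± 3.41, and it made up 10.7% ± 7.61, 7.43% ± 7.99 and 9.31% ± 6.56 in the treated model groups. By the edgeR test of OTU3 against model mice, the adjusted p was 0.0641, 0.224 and 0.0253 in these groups, with 10, 6 and 8 of 10 mice above the model mean. Single mice weighed on some of these means: without control mouse 4 the control mean was 5.26% for OTU1 and 0.388% for OTU2, and the model mean was 0.151% for OTU2 without model mouse 16 and 0.697% for OTU3 without model mouse 2. The table gives no taxonomic name for these OTUs.

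**Figure D1:**
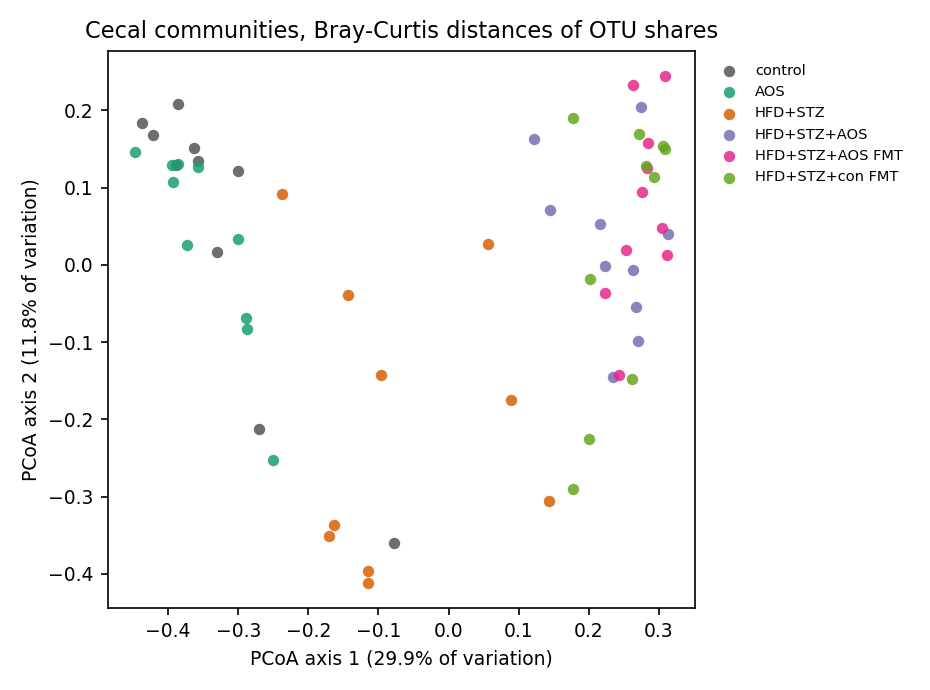
Principal coordinates of the Bray-Curtis distances between the 60 mice, 1 point per mouse, with the first axis (29.9% of variation) across and the second (11.8%) up. The treated model groups share the right side, control and AOS mice lie on the left except for 1 control mouse among the model mice, and the untreated model mice spread between them.

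The first comparison asks what high fat diet with STZ did to the community. A large block of OTUs that control mice carried was nearly absent from model mice. The 173 OTUs that were lower in model mice held 28.6% ± 13.4 of counts in control mice and 0.759% ± 0.42 in model mice, and 65 of them had no count in any of the 10 model mice. The 62 OTUs that were higher held together 0.457% ± 0.423 in control and 10.7% ± 5.3 in model mice. Both sets were picked by their difference in these same mice, which can enlarge these gaps. OTU3 rose at least 2440-fold and OTU25, found in 5 of 10 model mice and no control mouse, at least 717-fold (adjusted p = 0.000419 and 0.00203). OTU629, found in 9 of 10 control mice at 1.65% ± 3.14, and OTU24, found in all 10 at 0.798% ± 1.33, had no count in model mice and were at least 2590-fold and 1260-fold lower (adjusted p = 0.00122 and 0.000569). Without the mouse that held most of each, these bounds were 1050 (OTU3, model mouse 2), 325 (OTU25, model mouse 18), 1540 (OTU629, control mouse 3) and 751 (OTU24, control mouse 9). The 235 calls were made by edgeR's quasi-likelihood test among 726 OTUs, with 297 at an unadjusted p under 0.05. Lower calls were 73.6% of all under TMM factors and 53.5% under TMMwsp factors, which moved the median log2 fold change of all tested OTUs from -0.46 to 0.53, so the balance of rises and falls depends on the scaling.

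Model mice carried fewer OTUs than control mice. Observed OTUs per mouse numbered 444 ± 46.4 in model and 581.5 ± 90.2 in control mice (SD, n = 10 each, permutation test, adjusted p = 0.00504), a difference of -137.5, with 10 of 10 model mice below the control mean. The 2-sided permutation tests of 100000 resamples can give no p below 2e-05, and those of PERMANOVA and spread none below 1e-05. The Chao1 estimate differed by -143.9 (adjusted p = 0.006). The Shannon index was 3.6 ± 0.423 in model and 4.17 ± 0.774 in control mice, a difference that did not pass the test (permutation test, adjusted p = 0.148), although 10 of 10 model mice lay below the control mean. That outcome rests on control mouse 4, whose Shannon index was 2.33: without it the difference was -0.777 (adjusted p = 0.0104). The inverse Simpson index was 13 ± 7.06 against 28.9 ± 16.9 (adjusted p = 0.0886). Group membership accounted for 17.1% of the variation in Bray-Curtis distances (PERMANOVA, adjusted p = 0.00055), and the spread around the centroid did not differ detectably (0.471 ± 0.106 against 0.511 ± 0.0644, adjusted p = 0.35).

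**Figure D2:**
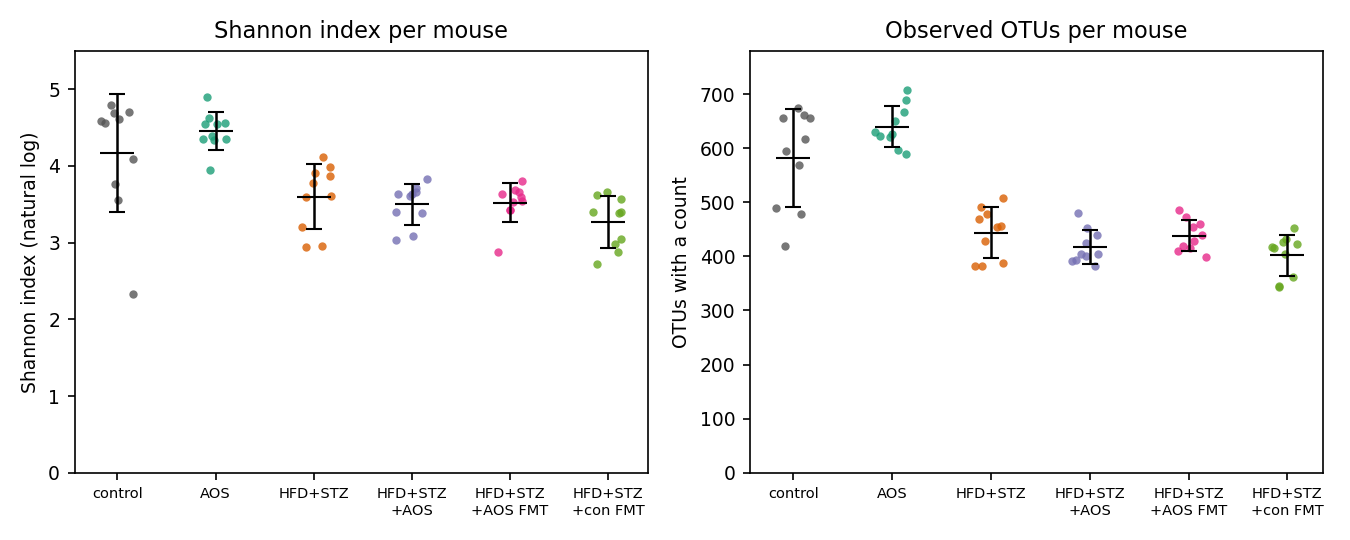
Shannon index (left, natural log) and number of observed OTUs (right) per mouse in each group, with 1 point per mouse and bars for the mean ± SD of 10 mice. All 4 groups on high fat diet with STZ have means of 402 to 444 observed OTUs, against 581.5 in control and 639.8 in AOS mice, and 1 control mouse has a Shannon index of 2.33.

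The second comparison asks what AOS did in mice without the model. OTU22 was the OTU called: it held 0.577% ± 0.655 in AOS mice, with counts in 8 of 10, and 1 count in 1 of 10 control mice. The ratio of pooled shares was 2720 (counting interval 487 to 107000; edgeR quasi-likelihood test, adjusted p = 0.00125). No OTU was called lower, and 106 of 773 OTUs had an unadjusted p under 0.05. Leaving out control mouse 5, the control mouse with the OTU22 count, left 0 calls, and leaving out control mouse 8 gave 4; leaving out control mouse 2, 9, 11 or 12 or AOS mouse 9 gave 2. DESeq2 called 15 OTUs, 46.7% of them lower, total-count scaling 5, 20% of them lower, and limma 0. The 173 OTUs lower in model mice held 26.0% ± 8.62 of counts in AOS mice, against 28.6% ± 13.4 in control mice. The 62 OTUs higher in model mice held 2.7% ± 5.79 in AOS mice (0.876% without AOS mouse 4), against 0.457% ± 0.423 in control mice, with 8 of 10 AOS mice above the control mean; neither share was tested. Observed OTUs averaged 639.8 ± 38.2 in AOS mice, a difference of 58.3 from control (permutation test, adjusted p = 0.119), and the Shannon index was 4.45 ± 0.247 (difference 0.286, adjusted p = 0.467). Group membership accounted for 6.46% of Bray-Curtis variation between AOS and control mice (PERMANOVA, adjusted p = 0.2). With distances that give rare OTUs more weight, the difference passed. The R2 was 0.0791 for the Aitchison distance (PERMANOVA, adjusted p = 0.00929) and 0.0743 for presence and absence (adjusted p = 0.0158). Spread was not tested for these distances, so part of both results can come from spread.

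AOS mice spread less around their group centroid than control mice, with a mean distance of 0.446 ± 0.0476 against 0.511 ± 0.0644 (permutation test of spread, adjusted p = 0.03). Their mean Bray-Curtis distance to the other mice of the group was 0.631 ± 0.0358, against 0.721 ± 0.047 in control mice. Control mouse 4 had the highest of these control distances, at 0.82, and spread was not tested without it. In AOS mice 239 OTUs had a count in all 10 mice, against 162 in control mice. Such numbers depend on the mice with fewest OTUs, and the lowest count of observed OTUs was 419 in control and 589 in AOS mice.

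The next 3 comparisons ask what AOS or a transplant did in model mice. All 3 treated groups differed from untreated model mice in many OTUs, most of them lower. AOS-treated model mice had 193 calls among 570 OTUs, 45 higher and 148 lower. AOS-donor recipients had 237 among 577, 60 higher and 177 lower, and control-donor recipients 214 among 568, 68 higher and 146 lower (edgeR quasi-likelihood test, with 238, 279 and 265 OTUs at an unadjusted p under 0.05). OTUs lower in AOS-treated model mice held 30.8% ± 18.8 of counts in untreated model mice and 0.957% ± 0.381 in the treated mice. For AOS-donor recipients the lower OTUs held 34.3% ± 18.8 in untreated and 1.40% ± 0.641 in treated mice. For control-donor recipients they held 31.1% ± 18.7 and 0.855% ± 0.479. The higher OTUs held 0.824% ± 1.59 in untreated and 16.4% ± 9.12 in treated mice, 1.26% ± 1.66 and 29.1% ± 9.09, and 3.10% ± 3.55 and 39.5% ± 15.6, in the same order. The OTUs of each set were picked by their difference in these same mice, which can enlarge these gaps, and the groups are separate mice. Without model mouse 16, the means of model mice for the higher OTUs were 0.324% and 0.805% in the first 2 contrasts. Lower calls were 76.7%, 74.7% and 68.2% of all. Under limma on centred log-ratio values they were 46.5%, 42.0% and 47.9%; under DESeq2 64.2% and 61.4% in the first 2 groups, and under TMMwsp 66.5% in the first. The median log2 fold change over all tested OTUs was -0.60, -0.84 and -0.34, against 0.32, 0.12 and -0.03 under limma.

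Named OTUs of these comparisons were mostly present on 1 side only. OTU67 rose at least 1420-fold in AOS-treated model mice, from 0 to 7 of 10 mice (adjusted p = 0.00263). OTU56 had 1 count over all untreated model mice and rose in each treated group by the edgeR test (adjusted p = 0.00334, 0.000367 and 8.65e-05). It was found in 4, 7 and 9 of 10 mice, with ratios of pooled shares of 595 (counting interval 106 to 23500), 2450 (440 to 96900) and 3410 (612 to 135000). In the first of these groups the call was lost with DESeq2 and limma (adjusted p = 0.844 and 0.15). OTU102 also rose in each treated group: it was in 9 of 10 AOS-treated model mice at 0.0801% ± 0.0725, in 10 of 10 AOS-donor recipients at 0.536% ± 0.322 and in 10 of 10 control-donor recipients at 0.744% ± 0.903. Its log2 fold changes were 6.14, 8.71 and 9.61 (edgeR, adjusted p = 0.00189, 2.59e-05 and 8.65e-05). OTU61 rose at least 742-fold in control-donor recipients, from 0 to 6 of 10 mice (adjusted p = 0.00318). Neither OTU61 nor OTU67 had a count in any other group, control and AOS mice included. OTU56 and OTU102 also had no count in control or AOS mice, so where these OTUs came from is not shown. OTU54, found in 7 of 10 untreated model mice at 1.15% ± 1.77, fell in each group: to 2 counts in AOS-treated model mice (ratio 2780, interval 770 to 23000), and at least 1890-fold and 1950-fold in the recipients (adjusted p = 0.00142, 0.00112 and 0.00151). OTU23, OTU48 and OTU1088 fell in each group as well. OTU23 had no count in AOS-treated model mice (at least 3210-fold lower, adjusted p = 0.00191) and 2 and 1 counts in AOS-donor and control-donor recipients (adjusted p = 0.000336 and 0.000234). OTU48 had 292 counts, no count (at least 3560-fold lower) and 85 counts in the 3 groups (adjusted p = 0.0293, 0.000755 and 0.0107). OTU1088 had 5 counts in AOS-treated model mice and none in the AOS-donor and control-donor recipients (at least 2200-fold and 2280-fold lower), with adjusted p = 0.00152, 0.000723 and 0.00114. Single mice held much of several of these OTUs. Without the mouse that held most, the fold was 297 for OTU56 in AOS-treated model mice (mouse 2), 1150 in AOS-donor recipients (mouse 3) and at least 345 for OTU61 (control-donor recipient 1). It was at least 1840 for OTU23 in AOS-treated model mice (model mouse 17) and at least 2230 for OTU48 in AOS-donor recipients (model mouse 18). For OTU54 it was 1770, at least 1200 and at least 1240 in the 3 groups (model mouse 15).

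**Figure D3:**
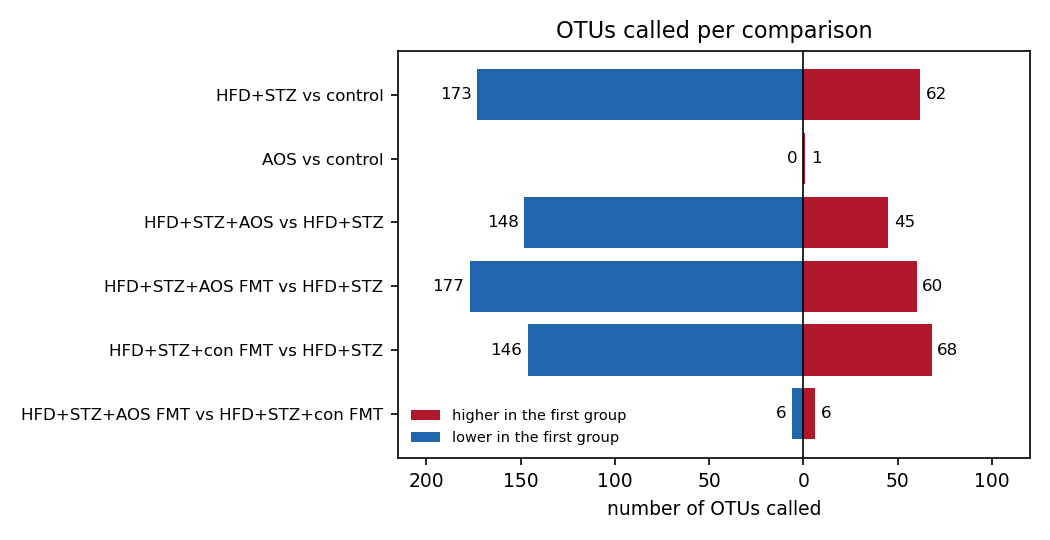
Number of OTUs called by edgeR's quasi-likelihood test at an adjusted p under 0.05 in each comparison, with OTUs higher in the first-named group to the right of 0 and lower ones to the left. The 3 comparisons of treated with untreated model mice give 193 to 237 calls, against 12 between the 2 kinds of recipient and 1 for AOS in mice without the model.

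The OTU lists of the 3 treatments overlapped more than independent lists would. Over the 531 OTUs tested in both, AOS-treated model mice and AOS-donor recipients shared 24 higher and 128 lower OTUs. AOS-treated model mice shared 29 and 113 with control-donor recipients, and the 2 kinds of recipient shared 43 and 124. No OTU was called in opposite directions in any of these pairs. Independent lists of these sizes would share 2.46, 3.02 and 5.46 higher and 46.3, 37.9 and 44.9 lower OTUs. The same untreated model mice enter each of these comparisons, which adds to the overlap. With these mice split into 2 sets of 5, so that the 2 lists shared no mouse, the median overlap over 100 splits was 6, 6 and 21 higher and 25, 22 and 28.5 lower OTUs. Independent lists of the sizes found in these splits would share a median of 1.68, 1.19 and 5.4 higher and 5.93, 5.36 and 7.85 lower OTUs. The 105 OTUs that fell in all 3 groups held 25.9% ± 18 of counts in untreated model mice, 22.9% ± 12.5 in control and 20.6% ± 7.09 in AOS mice, and 0.51% ± 0.154, 0.51% ± 0.263 and 0.484% ± 0.34 in the treated groups. The 23 that rose in all 3, OTU2 among them, held 0.69% ± 1.61 in untreated model and 0.771% ± 1.23 in control mice, and 13.5% ± 9.49, 21.4% ± 5.95 and 21.8% ± 10.5 in the treated groups. Nearly all of this share was OTU2: the other 22 held 0.0469% ± 0.054 in untreated model and 0.035% ± 0.0245 in control mice, and 1.26% ± 0.857, 2.56% ± 1.52 and 2.46% ± 1.85 in the treated groups. With OTU2 included, the model mean was 0.184% without model mouse 16 and the control mean 0.424% without control mouse 4.

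Communities of the treated groups were set apart from untreated model mice and spread less around their centroids. Group membership accounted for 21.5%, 29.2% and 23.5% of variation between untreated model mice and AOS-treated model mice, AOS-donor recipients and control-donor recipients (PERMANOVA, adjusted p = 4e-05 each). Spread around the centroid was 0.349 ± 0.0634, 0.297 ± 0.0561 and 0.35 ± 0.0873, against 0.471 ± 0.106 in untreated model mice (adjusted p = 0.0084, 6e-05 and 0.019), so part of each PERMANOVA result can come from spread. Mean distance to the other mice of the group was 0.49 ± 0.0472, 0.42 ± 0.0402 and 0.494 ± 0.0681, against 0.669 ± 0.0819 in untreated model mice. Diversity did not change detectably: the Shannon index was 3.50 ± 0.266, 3.52 ± 0.254 and 3.27 ± 0.335, against 3.6 ± 0.423 in untreated model mice (adjusted p = 0.625, 0.625 and 0.148). Observed OTUs numbered 417.5 ± 31.1, 438.4 ± 28.8 and 402 ± 38.1, against 444 ± 46.4 (adjusted p = 0.181, 0.75 and 0.0852).

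The study's title makes a return toward the control community the next question. By distance, treated model mice lay farther from the control mice than untreated model mice did. The mean Bray-Curtis distance to control was 0.79 ± 0.0355 in untreated model mice, 0.841 ± 0.0147 in AOS-treated model mice, 0.843 ± 0.0188 in AOS-donor recipients and 0.844 ± 0.0233 in control-donor recipients. The differences were 0.0503, 0.0529 and 0.0532 (permutation test, adjusted p = 0.00126, 0.00126 and 0.00136). In each treated group, 10 of 10 mice lay above the mean of the untreated model mice. Control mice had a mean distance of 0.721 ± 0.047 to one another.

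**Figure D4:**
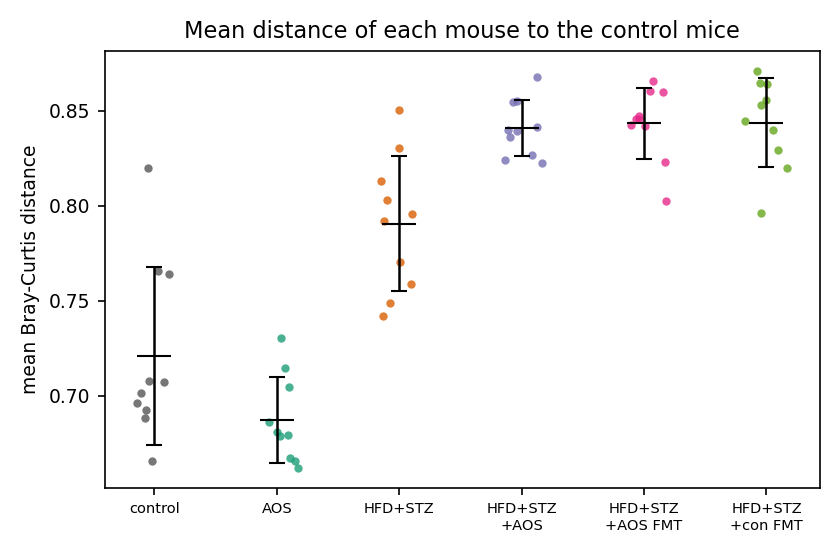
Mean Bray-Curtis distance of each mouse to the control mice (to the other 9 for a control mouse), with 1 point per mouse and bars for the mean ± SD of 10 mice; the axis does not start at 0. The treated model groups have means of 0.841 to 0.844, above the untreated model mice at 0.79.

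By OTU, the block that model mice lacked stayed low. The 173 OTUs lower in model mice held 0.889% ± 0.589 of counts in AOS-treated model mice, 0.756% ± 0.305 in AOS-donor recipients and 1.09% ± 1.41 in control-donor recipients, against 28.6% in control mice. Without control-donor recipient 7, which held 4.96%, the last of these means was 0.664%. In these groups 102, 104 and 111 of them had no count in any mouse. By the edgeR test, 1, 3 and 6 of the 173 were higher than in untreated model mice. Of the 62 OTUs higher in model mice, 15, 19 and 17 were lower in the treated groups than in untreated model mice. The 62 together held 16.8% ± 7.95, 13.1% ± 8 and 13.5% ± 7.52 of counts, against 10.7% ± 5.3 in untreated model mice, but OTU3 alone made up the excess. The other 61 held 6.18% ± 1.34, 5.62% ± 1.81 and 4.22% ± 1.93, against 8.94% ± 3.19 in untreated model and 0.457% ± 0.423 in control mice. The 62 were picked as higher in these same model mice, so a lower share in other mice needs no treatment effect, and neither sum was tested. In all, 16, 22 and 23 of the 235 model OTUs moved back, and 10, 9 and 9 moved further from control. Only 87, 89 and 90 of the 235 were common enough in these groups to be tested. Untreated model mice enter both contrasts, and in 100 simulations with no treatment effect 0.31 OTUs moved back on average and at most 6. The simulations drew each OTU independently of the others, so they can understate what real communities give and cannot decide the question. With the untreated model mice split into 2 sets of 5, 1 for each contrast, a median of 4, 6 and 4 OTUs moved back and 5, 7 and 6 moved further. Once no mouse was shared, moving back was thus no more common than moving further. Model mice 2, 7 and 9 lay nearest to the treated model mice, at mean Bray-Curtis distances of 0.63, 0.577 and 0.59. The other model mice lay at 0.685 to 0.889. In a comparison chosen after this was seen, leaving out these 3 gave 26 and 34 OTUs that moved back in AOS-treated model mice and AOS-donor recipients. Leaving out the mice nearest to the treated groups widens the contrast by selection, so this rise needs no treatment effect. No value is given here for control-donor recipients, so the rise is not shown to be particular to these 2 groups.

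**Figure D5:**
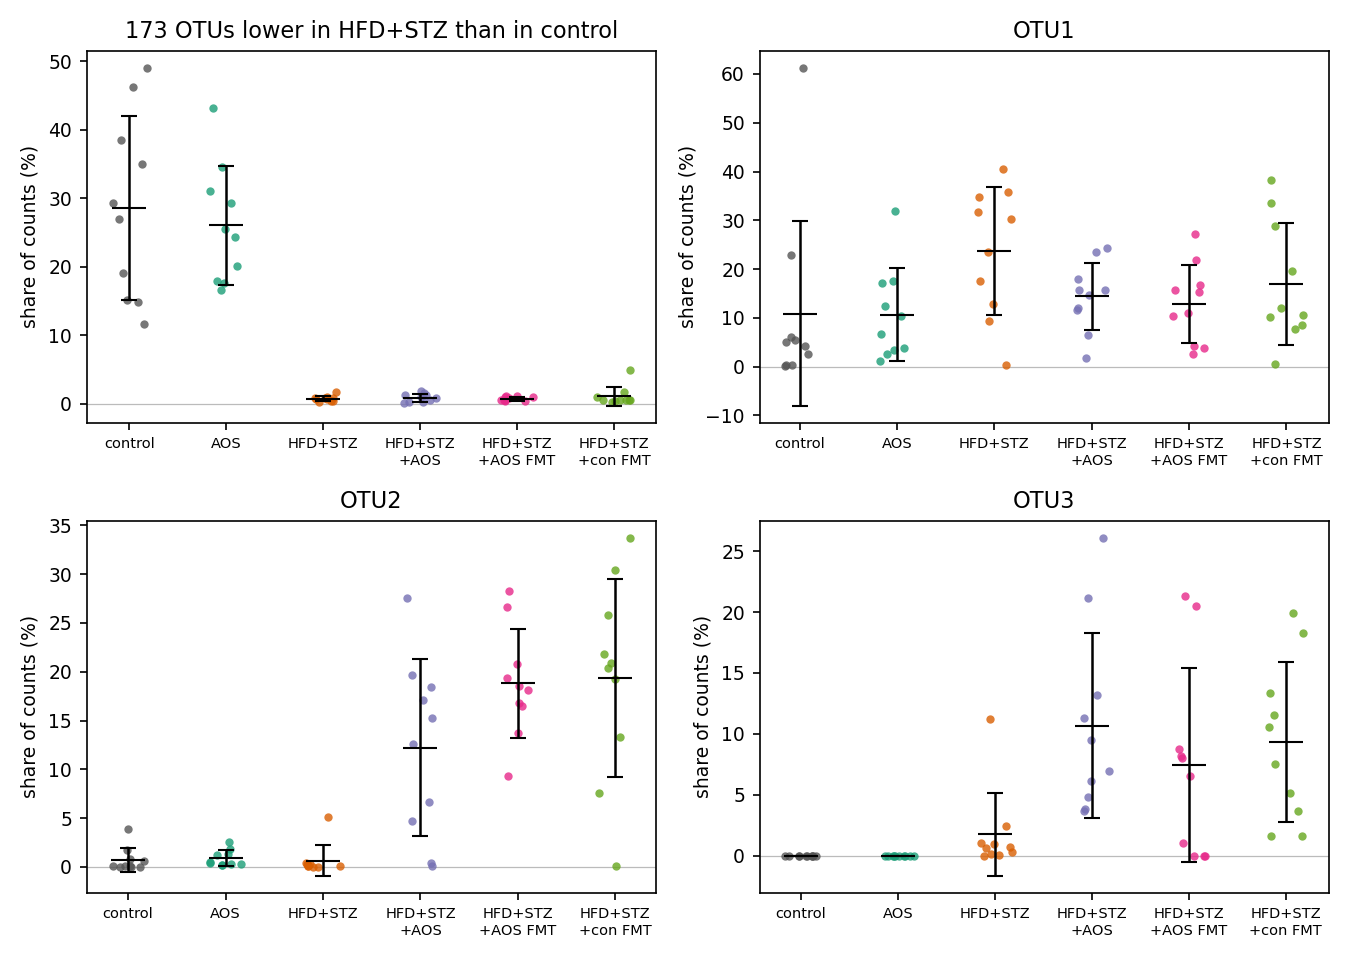
Share of counts per mouse, in percent, of the 173 OTUs lower in model than in control mice (upper left) and of OTU1, OTU2 and OTU3, with 1 point per mouse and bars for the mean ± SD of 10 mice, which can reach below 0 for skewed shares. The 173 OTUs hold 28.6% and 26.0% in control and AOS mice and at most 1.09% on average in the 4 groups with the model, and OTU2 has its 3 highest means in the treated model groups.

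The last comparison asks whether the 2 kinds of donor gave different communities. Few OTUs passed the test, which called 33.3% of OTUs changed by a log2 fold of 2 in simulated data. OTU2 held 18.8% and 19.3% and OTU1 12.9% and 17% (edgeR, adjusted p = 0.905 and 0.667). Of 485 OTUs, 12 were called, 6 higher and 6 lower in AOS-donor recipients, and 72 had an unadjusted p under 0.05. OTU30 was in 6 of 10 AOS-donor recipients at 1.26% ± 2.68 and at 8 counts over 3 control-donor recipients (log2 fold change 9.58, SE 2.15, adjusted p = 0.0218). OTU30 was also in 10 of 10 control mice (2455 counts) and 10 of 10 AOS mice (753 counts). Untreated model mice had it in 9 of 10 (2502 counts) and AOS-treated model mice in 4 of 10 (386 counts). Control-donor recipients thus nearly lacked an OTU that every control mouse carried. Between the recipients, its ratio of pooled shares was 801, and 378 without AOS-donor recipient 4. OTU172 was in 7 of 10 at 0.149% ± 0.278 and at 2 counts in 1 control-donor recipient (ratio 371, counting interval 102 to 3070, adjusted p = 0.0109; ratio 185 without AOS-donor recipient 6). OTU61, in 6 of 10 control-donor recipients, had no count in AOS-donor recipients (at least 763-fold lower, adjusted p = 0.0305; at least 354-fold without control-donor recipient 1). Neither OTU172 nor OTU61 had a count in any control or AOS mouse. None of these 3 named OTUs passed under limma (adjusted p = 0.416, 0.146 and 0.205), which called 0 OTUs. OTU30 did not pass under DESeq2 (adjusted p = 0.58), which called 13. Leaving out AOS-donor recipient 7 left 3 calls, control-donor recipient 1 or 4 left 4, and control-donor recipient 5 or 7 left 7. Under total-count scaling, which gave 13 calls, 38.5% were lower, against 50%.

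Whole communities of the 2 kinds of recipient did not differ by Bray-Curtis distance, with 5.56% of variation between them (PERMANOVA, adjusted p = 0.38). They differed by presence and absence of OTUs (R2 0.0896, PERMANOVA, adjusted p = 0.00121) and by Aitchison distance (R2 0.0823, adjusted p = 0.00929). Spread was not tested for these distances, so part of both results can come from spread. By Bray-Curtis distance, the spread around the centroid was 0.297 ± 0.0561 in AOS-donor and 0.35 ± 0.0873 in control-donor recipients. That difference did not pass the permutation test (adjusted p = 0.15). The Shannon index differed by 0.251 and observed OTUs by 36.4 (adjusted p = 0.148 and 0.0844). No difference was detected in nearness to the group that the donors were named for: the mean distance to control minus the mean distance to AOS mice was 0.0216 ± 0.0125 in AOS-donor and 0.0224 ± 0.00623 in control-donor recipients (permutation test, p = 0.862). By Bray-Curtis distance both kinds lay nearer to AOS than to control mice, but so did the control mice themselves (0.687 to AOS mice, 0.721 to one another). By Aitchison distance both lay farther from AOS mice (120 and 118) than from control mice (117 and 115).

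The difference between AOS-treated and untreated model mice was set against that between AOS and control mice. Of 963 OTUs, 205 passed the edgeR test of the difference of differences, and 329 had an unadjusted p under 0.05. The value in model mice was more positive for 33 and more negative for 172. OTU67, OTU56 and OTU102 rose in AOS-treated model mice but had no count in control or AOS mice. Their standard errors in this test were 39100, 20100 and 17500, so they could not be called. The balance of 33 and 172 may thus partly reflect which OTUs could be estimated. Of the 205, 111 were also called in AOS-treated against untreated model mice. In AOS-donor and control-donor recipients against the same untreated mice, 107 and 101 of the 205 were called. The label of the control-donor recipients names no AOS, so these 101 were called in a contrast without it. Untreated model mice enter both tests, however, which adds to this overlap. Of all OTUs tested, 237 of 577 were called in AOS-donor and 214 of 568 in control-donor recipients. The contrast includes anything besides AOS that differed between AOS-treated and untreated model mice, which this test does not separate from AOS.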

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

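The tests of AOS and of separate cohorts as explanations, and the difference of differences in observed OTUs, were chosen after the results were seen. Mice that stood far from the other 9 of their group by Dixon's criterion were sought in 80 groups of values, and 19 had one, where chance gives about 1 in 20. Diversity, depth and distance measures gave 4 of 41, and shares of named or dominant OTUs, which are skewed, 15 of 39.

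Treated model mice lay farther from control mice than untreated model mice did, whichever treatment they received: the 3 treated groups together exceeded the untreated by 0.0521 in Bray-Curtis distance (permutation test, p = 4e-05). Depth did not account for it, since the difference was 0.0522 after rarefying (p = 4e-05). Dominant OTUs did not account for all of it. Without the 10 most abundant ones the difference was smaller but remained, at 0.0393 (permutation test, p = 6e-05). AOS as the only cause is argued against by the control-donor recipients, which differed from untreated model mice by 0.0532. Separate cohorts, cages or batches cannot be told apart from treatment, as no label gives them: of 347 OTUs common in control and AOS mice, 44 had no count in any treated model mouse, and 28 of these were seen in untreated model mice. Any procedure shared by the 3 treated groups also stays open, as untested.

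Control mouse 4 had a Shannon index of 2.33, far below the other control mice, with an OTU1 share of 61.28% and an OTU2 share of 3.875%, each far above theirs. Depth did not account for the index, which was 2.32 at the common rarefied depth, where the other control mice had 3.58 to 4.79. A single dominant OTU could account for it: without OTU1 the index was 4.29, within the 3.55 to 4.86 of the others. A library of an untreated model mouse under a control label was tested with the 68 OTUs higher in model mice in a fit without this mouse. They summed to 4.23% in control mouse 4, below the 5.68% to 35.8% of model mice. The sum was also above the 0.265% to 1.66% of the other control mice. The 68 were picked as high in these same model mice and not in mouse 4, so this test cannot decide the question. No biological explanation was tested.

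Among other values far from the rest of their group, AOS mouse 10 had a total of 37776 counts. AOS-donor recipient 18 had a Shannon index of 2.877. Model mouse 14 had a mean distance of 0.86 to the other model mice. Large shares in single mice were those of OTU3 in model mouse 2 (11.23%), OTU25 in model mouse 18 (2.642%), OTU23 in model mouse 17 (9.586%), OTU2 in model mouse 16 (5.07%), OTU1 in AOS mouse 3 (31.99%), OTU56 and OTU102 in AOS-donor recipient 3 (3.086% and 1.337%) and OTU61 in control-donor recipient 1 (2.641%). Small shares in groups otherwise at or near 0 were those of OTU22 in control mouse 5 (0.002874%), OTU56 in model mouse 16 (0.002194%), OTU102 in model mouse 9 (0.006635%), OTU172 in control-donor recipient 13 (0.003977%) and OTU3 in AOS mouse 8 (0.01319%).

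The difference between mice with and without AOS was not alike with and without the model for 205 OTUs by the edgeR test. This contrast includes anything besides AOS that differed between AOS-treated and untreated model mice, and does not separate the 2. For observed OTUs the difference of differences was -84.8 (permutation test, p = 0.0211, adjusted p = 0.0422 over 2 measures), and for the Shannon index -0.383 (p = 0.217). Observed OTUs depend on depth: between AOS and control mice they differed by 58.3 as counted and by 48.9 at the common rarefied depth. The difference of differences was not tested at that depth. Of 100 regroupings of the mice, the real one included, 2 gave as many interaction OTUs. The highest other gave 211 and the median of the others was 22, so regrouping alone usually gave calls in this test. Mice were regrouped within those without the model and within model mice. At the 0.05 level this excludes only that AOS labels made no difference in either. The 193 calls between AOS-treated and untreated model mice already go against that, so regrouping cannot decide on a difference of differences. The permutation tests of observed OTUs and the Shannon index regrouped mice alike and share this limit.

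Regrouping tested the counts of the 6 comparisons in the same way, over 100 splits each. For model against control mice 1 split, the real one, gave as many as 235 OTUs (highest other 89). The real split alone also gave as many for AOS-treated model mice (193 OTUs, highest other 103) against model mice. So it did for AOS-donor recipients (237, highest other 69) and control-donor recipients (214, highest other 67). Counts this large were thus rare among splits of single mice. Such splits cannot exclude shared cages or batches as the source, since no label gives them. Between the 2 kinds of recipient the real split alone gave 12 (highest other 4), but with 1 mouse left out as few as 3 were called. For AOS against control mice 29 splits gave at least 1 OTU, so chance was not excluded, and the split that gave 44 points to a structure among these samples, whose nature was not tested.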

How the results depend on the processing

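Leaving out model mice 2, 7 and 9 (numbers up to 10), leaving control mouse 4 out of the reference and leaving out each mouse for the Shannon index were chosen after the results were seen. Of the values that answer a comparison, 101 kept their direction and their side of the threshold or stayed within 1.5 times, 32 moved, 5 passed the threshold newly and 2 reversed; for each change not explained here, the cause was not tested. Of 20 named OTUs with their comparisons, 15 kept direction and call in all alternatives run, 5 lost the call in at least 1 and 0 reversed. With no filter, more OTUs were tested and 452 were called for model against control mice and 369, 422 and 381 for AOS-treated model mice, AOS-donor recipients and control-donor recipients against model mice. Among OTUs of at least 0.1% mean share, which are fewer, the calls were 52, 47, 47 and 49, 2 between the recipients and 63 in the interaction, and 4, 3 and 5 moved back. With limma, 114 were called for AOS-treated model mice and 0 between the recipients. For AOS against control mice, limma called 0, total counts 5, DESeq2 15, rarefied counts 2 and a fit of all groups 12. With the mouse number as a replicate block, over the 3, 8, 3, 5, 4 and 5 numbers shared, the calls were 0, 1, 0, 21, 2 and 0, and 0, 1, 0, 48, 0 and 6 for the same mice without it; fewer mice enter, and the numbers showed no pairing. Over the 5 shared numbers of the replicate block the Shannon difference of AOS-donor recipients and model mice reversed to 0.0484 (p = 0.812), from the choice of mice, since a block leaves the mean difference of complete pairs as it is. Without model mice 2, 7 and 9, 26 and 34 OTUs moved back in AOS-treated model mice and AOS-donor recipients. These 3 lay nearest to the treated mice, so leaving them out favours such a rise by selection. The nearness to AOS mice reversed with Aitchison distance (0.208, p = 0.352). Observed OTUs in place of Shannon passed for model against control mice (-137.5). PERMANOVA R2 passed with Aitchison distance for AOS against control mice (0.0791) and between recipients (0.0823), and on presence (0.0743 and 0.0896).

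With 1 mouse left out, calls ranged from 194 to 248, 0 to 4, 145 to 211, 198 to 256, 176 to 233 and 3 to 15 over the 6 comparisons in the order of the report, and from 179 to 229 in the interaction. For AOS against control mice, 0 were called without control mouse 5, 4 without control mouse 8 and 2 without control mouse 2, 9, 11 or 12 or AOS mouse 9. Between the recipients, 3 were called without AOS-donor recipient 7, 4 without control-donor recipient 1 or 4 and 7 without 5 or 7. Shannon differences ranged from -0.777 to -0.501, 0.082 to 0.356, -0.169 to -0.0395, -0.149 to -0.00592, -0.4 to -0.267 and 0.19 to 0.323, and the first passed without control mouse 4 (-0.777, adjusted p = 0.0104, permutation test). Genus-level alternatives, taxon lists and phylum shares were not run, since the table has no taxonomy, and a count of 0 allows a share of up to 0.00862% in the shallowest mouse.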

Other observations

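The comparisons in this part were chosen after the results were seen. Treated model mice differed from control mice in more OTUs than untreated model mice did. AOS-treated model mice had 526 OTUs called against control mice among 737, with 175 higher and 351 lower. AOS-donor recipients had 539 among 731 (189 higher, 350 lower) and control-donor recipients 498 among 712 (157 higher, 341 lower), by edgeR's quasi-likelihood test. The OTUs that were lower held 62.2% ± 16.1, 66.1% ± 18.2 and 56.8% ± 15.8 of counts in control mice (SD, n = 10) and 2.08% ± 0.958, 1.97% ± 0.887 and 1.27% ± 0.68 in the treated groups. PERMANOVA assigned 33.8%, 38.1% and 33.8% of variation to these contrasts (adjusted p = 3.3e-05 each). The difference between these numbers of OTUs and the 235 of untreated model mice was not tested. The treated groups also spread less around their centroids (0.349, 0.297 and 0.35, against 0.471 in untreated model mice). Less spread can make calls easier to reach, so these numbers do not measure the size of a change. The summed shares are of OTUs picked in these same mice.

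Among themselves, the 3 treated groups differed in 12 to 43 OTUs by the edgeR test. AOS-donor recipients differed from AOS-treated model mice in 34 of 491 OTUs, 16 higher and 18 lower, and control-donor recipients in 43 of 490, 21 higher and 22 lower. PERMANOVA assigned 10.2% of variation to the first contrast (adjusted p = 0.034) and 8.27% to the second (adjusted p = 0.1). Mean Bray-Curtis distances were 0.48 between AOS-treated model mice and AOS-donor recipients, 0.51 between AOS-treated model mice and control-donor recipients, and 0.46 between both kinds of recipient. Distances of these groups to untreated model mice were 0.696, 0.721 and 0.714.

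OTUs found in all 10 mice of a group numbered 162 in control, 239 in AOS, 84 in untreated model, 141 in AOS-treated model mice, 182 in AOS-donor and 127 in control-donor recipients. Of the 162 in control mice, 3 had no count in any untreated model mouse, and 19, 20 and 23 had none in the treated groups in the same order. Conversely, 58 of the 162 were in all 10 untreated model mice, and 67, 71 and 64 in all 10 mice of the treated groups. Of 253 OTUs found in at least 24 of the 30 treated model mice, 13 had no count in any control or AOS mouse, and 11 of these were seen in an untreated model mouse.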
